A study of Mus musculus with 11 samples.

How the data were processed

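The samples were 11 bulk RNA-seq libraries of distant MOC2 tumours, 4 labelled IgG, 4 labelled 3xTx and 3 labelled 3xTxNK, and groups were taken from the treatment given in the labels. Per the labels' protocols, tumours were collected on day 12 and homogenised with ceramic beads in Trizol, RNA was isolated with RNeasy Mini columns, and libraries were built from 1 ug of RNA with a stranded TruSeq mRNA kit. Per the submitters' processing notes, the authors used STAR, RSEM and the mouse build GRCm39. Versions, annotation release, strand setting, trimming and filters are not given in the sources used here. The deposited values are expected counts per gene, not normalised, 1 column per library, and the file held them as whole numbers already (0 values were not whole), so rounding changed nothing. It lists 51912 Ensembl genes, each paired with a symbol, of which 18160 had no count in any library. The annotation at hand is of another mouse build, so no coordinates are given, and gene symbols and identifiers are those of the file. Where a symbol belonged to more than 1 identifier (98 symbols), it was kept for the identifier with the highest total count. List members that the file does not hold under the listed symbol (Cd244a, Fdcsp and Ahsp) count as not measured. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and members of multigene families (granzymes, Klr receptors, Gbp, Ifit, H2-Q, Serpina3 and receptor segments) can share reads.

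Computed here with R 4.3.3 were TMM factors, the filterByExpr filter by group (minimum count 10, minimum total 15), which kept 19806 genes, and edgeR 4.0.16's quasi-likelihood fit with 1 mean per group and no covariate. All 11 libraries shared 1 estimate of the spread because groups hold 3 or 4 libraries, and the common dispersion was 0.0633. The 3 pairwise contrasts were tested with Benjamini-Hochberg adjustment and a threshold of 0.05. SEs are the absolute log2 fold change over the square root of F, and 95% intervals use the t distribution with the fit's total degrees of freedom. CPM are TMM-scaled, and log2 CPM for principal components (1000 most variable genes) and list means used a prior count of 2. The floor for a group with no counts is 3 counts over that group's total, and floors and intervals of counts cover counting error only.

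There were 26 gene lists of cell types and pathways, fixed from textbook knowledge before the data were examined, including markers of tissue that a dissected tumour can carry. The 24 lists with at least 5 tested members were tested per comparison with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists. Camera with an estimated correlation was run beside it, and so was fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. For each list the members past the threshold were counted over all genes and adjusted over the list alone. Named genes followed a rule also fixed before the data were examined. It took, per comparison, the 5 largest rises and 5 largest falls among called genes with a mean of at least 1 CPM in the higher group and libraries that do not overlap, leaving out predicted genes (Gm or Rik symbols). It added up to 2 called members of smallest p per list, and a fixed set reported whatever its outcome (Ncr1, Klrb1c, Cd3e, Cd8a, Cd4, Gzmb, Prf1, Ifng, Cxcl9, Cd274, Pdcd1, Foxp3, H2-Ab1, Krt14, Col1a1 and Egfr). Some genes that this rule takes are not reported here.

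The procedure was tested on simulated data drawn from the real means and library sizes with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes all had a mean of at least 1 CPM, so recovery at lower levels was not tested. For 3xTx against IgG, with 19377 genes tested, the procedure recovered 61% and 95% of the changed genes and called 8 unchanged genes. For 3xTxNK against 3xTx, with 19381 genes, it recovered 57% and 89% and called 9 unchanged genes, and for 3xTxNK against IgG, with 19353 genes, 62% and 94% and 6. Overlaps of calls between comparisons that share libraries were set beside 50 simulations of unchanged groups, the overlap of independent lists, and 6 fits with the shared group split into pairs of libraries.

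Alternatives fixed before the data were examined were DESeq2 size factors, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of at least 1 CPM in 3 libraries, a fit of only the groups compared, the replicate number of the title or of the description as a block, the skeletal muscle list as a covariate, a threshold of 0.1, other list tests, and leaving out each library in turn. Chosen after seeing the data were robust empirical Bayes, thinning every library to the shallowest (4131503 counts), leaving out the shallowest library and thinning the others to the smallest IgG total, removing mitochondrially encoded genes, and the mitochondrial share as a covariate. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out of the reported fit.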

Results

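Messenger RNA was measured in the untreated distant tumours of C57BL/6 mice that carried MOC2, a murine head and neck squamous cell carcinoma line, on both flanks. Only the primary tumour was treated, and the distant tumour was collected on day 12. The 11 libraries fell into 3 groups. The IgG group (n = 4) had received control immunoglobulin in the primary tumour. The 3xTx group (n = 4) had received radiation of the primary tumour together with intratumoral interleukin-2, a growth factor of T and natural killer (NK) cells, and intratumoral cetuximab, an antibody against the EGF receptor. The group labelled 3xTxNK (n = 3) had received the same treatment and an antibody against NK1.1, a surface protein of NK cells, given to deplete them. The labels do not say whether replicates are separate animals, so each p-value measures the spread between these samples.

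Total expected counts were 22598183, 19295569, 22644061 and 23220192 in IgG replicates 1 to 4. They were 36004702, 4131503, 81290005 and 76058166 in 3xTx replicates 1 to 4, and 50189411, 48157012 and 36118797 in 3xTxNK replicates 1 to 3. The 3xTx group thus held both the shallowest and the deepest library. Depth also went with the group, since every treated library except 3xTx replicate 2 was deeper than every IgG library. Mitochondrially encoded genes took 3.8 ± 0.576% of the counts in IgG (SD, n = 4), 5.07 ± 1.18% in 3xTx (n = 4) and 4.92 ± 1.44% in 3xTxNK (n = 3), with the highest share, 6.77%, in 3xTx replicate 2. Correlations of log2 normalised counts between replicates were 0.9468 to 0.9643 in IgG, 0.9412 to 0.9817 in 3xTx and 0.9777 to 0.9823 in 3xTxNK. The first principal component held 28.3% of the variance of the 1000 most variable genes and set 3xTx replicate 2 apart at -74.3, and the second held 19.1%. Levels below are TMM-normalised CPM, counts scaled to a common library total, as mean ± SD. Fold changes are on the log2 scale with their SE, and adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 19806 genes.

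Klrb1c (ENSMUSG00000030325), the gene of NK1.1, was not lower in the libraries labelled 3xTxNK than in 3xTx. It stood at 1.7 ± 0.185 CPM in 3xTxNK (n = 3) and 1.78 ± 0.603 CPM in 3xTx (n = 4), a log2 fold change of -0.11 with a 95% interval of -1.06 to 0.84, against 0.759 ± 0.443 CPM in IgG (n = 4). Ncr1, the gene of the NK receptor NKp46, was at 0.254 ± 0.304 CPM in 3xTxNK and 0.716 ± 0.559 CPM in 3xTx (log2 fold change -1.65, interval -3.47 to 0.18, adjusted p = 0.425). Ncr1 was near the lower end of what these depths resolve. The NK1.1 transcript does not check the 3xTxNK label, and every direction below that involves 3xTxNK rests on the labels.

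The comparison of 3xTx with IgG asks what treatment of the primary tumour did at the untreated site. Transcripts of T cells, cytotoxic effectors, interferon gamma response and MHC class II presentation were higher in 3xTx, and matrix transcripts were lower. Cd8a (ENSMUSG00000053977), a chain of the co-receptor of cytotoxic T cells, was at 28.3 ± 2.4 CPM in 3xTx (n = 4) against 3 ± 1.17 CPM in IgG (n = 4), a log2 fold change of 3.24 ± 0.26 (adjusted p = 1.99e-05). Cxcl9 (ENSMUSG00000029417), an interferon-induced chemokine that attracts T cells, was at 130 ± 31.3 CPM against 7.36 ± 2.14 CPM, a log2 fold change of 4.16 ± 0.3 (adjusted p = 1.06e-05). H2-Ab1 (ENSMUSG00000073421), a chain of MHC class II, was at 99.7 ± 21.9 CPM against 17.9 ± 4.32 CPM, and Col3a1, a fibrillar collagen, at 1480 ± 237 CPM against 2710 ± 276 CPM. In all, 1934 of 19806 genes (9.76%) changed, 1149 upward and 785 downward. In 16.1% of the tested genes every library of one group lay above every library of the other, where chance gives 2.86%.

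Of the 19 tested genes of T cell identity and receptor signalling, 18 rose in 3xTx, also 18 adjusted over the list alone, and the list's median log2 fold change was 3.03 (camera adjusted p = 8.17e-45, and 0.00684 with an estimated correlation). Bcl11b, a transcription factor of the T lineage, was at 3.07 ± 0.154 CPM against 0.2 ± 0.107 CPM, Trbc2, a constant segment of the T cell receptor, at 15.8 ± 1.59 CPM against 1.49 ± 0.347 CPM, and Cd3e at 8.56 ± 1.15 CPM against 1.1 ± 0.597 CPM. All 19 CD8 and cytotoxic effector genes rose, with a median of 3.17 (adjusted p = 2.46e-45, and 0.0115 with an estimated correlation). Among them Gzmb, a granzyme, had a log2 fold change of 2.37 ± 0.39, Prf1, the pore-forming perforin, 2.2 ± 0.37, and Ifng, interferon gamma itself, 2.71 ± 0.64. Granzymes C to F in this list are closely related copies that can share reads, so their single values are uncertain. Cd4 rose by 1.23 ± 0.29 from 3.43 ± 1.09 CPM to 8.16 ± 2.74 CPM. The call of Cd4 failed without 3xTx replicate 1 (adjusted p = 0.0544) and that of Ifng without 3xTx replicate 3 (adjusted p = 0.0531).

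Inhibitory checkpoint genes rose in 8 of 12 cases, or 10 adjusted over the list alone, with a median of 1.64 (adjusted p = 3.19e-12, and 0.0158 with an estimated correlation). Pdcd1, the gene of PD-1, was at 9.72 ± 1.67 CPM against 0.785 ± 0.34 CPM, and Cd274, the gene of its ligand PD-L1, at 51.5 ± 7.27 CPM against 16.6 ± 3.38 CPM. Of 10 regulatory T cell genes, Ctla4 and Il2ra rose, both also expressed by activated T cells, with 2 adjusted over the list alone. That list's median was 0.26 (adjusted p = 0.0308), and its call was lost with an estimated correlation (adjusted p = 0.26), and also without IgG replicate 2 or 3xTx replicate 3 (highest adjusted p = 0.117). Foxp3, the transcription factor of regulatory T cells, was at 1.05 ± 0.83 CPM in 3xTx and 1.01 ± 0.18 CPM in IgG (log2 fold change 0.21, interval -0.77 to 1.19). In the interleukin-2 signalling list 4 genes rose, among them the receptor chain Il2rb (22 ± 1.2 CPM against 5.18 ± 0.834 CPM) and the interleukin-7 receptor Il7r (log2 fold change 3.41 ± 0.3). Socs2, a suppressor of cytokine signalling, fell, and 8 members did not pass (5 up and 1 down adjusted over the list alone). The list's median was 0.32 (adjusted p = 1.18e-05, and 0.0177 with an estimated correlation).

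Of 15 NK cell genes, Klrb1b, Klre1, Klri2 and Txk rose (6 adjusted over the list alone), with a median of 1.64 (adjusted p = 2.19e-05, and 0.0158 with an estimated correlation). Klri2 was at 1.55 ± 0.942 CPM against 0.0829 ± 0.0962 CPM, and its receptor family can share reads. Neither Klrb1c (adjusted p = 0.0852) nor Ncr1 (adjusted p = 0.185) passed. Macrophage and monocyte genes rose in 11 of 18 cases (11 adjusted over the list alone), with a median of 0.82 (adjusted p = 2.17e-11, and 0.0264 with an estimated correlation). Csf1r, the receptor of macrophage colony-stimulating factor, was at 145 ± 23.4 CPM against 65.7 ± 8.93 CPM, and Adgre1, the gene of F4/80, at 35.9 ± 10 CPM against 11 ± 3 CPM. MHC class II genes rose in 8 of 11 cases (8 adjusted over the list alone), with a median of 1.70 (adjusted p = 2.58e-19, and 0.0115 with an estimated correlation).

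Interferon gamma response genes rose in 19 of 22 cases (21 adjusted over the list alone), with a median of 1.37 (adjusted p = 1.6e-25, and 0.028 with an estimated correlation). Chemokines and their receptors rose in 14 of 27 cases (15 up and 2 down adjusted over the list alone), with a median of 0.74 (adjusted p = 1.93e-13, and 0.0115 with an estimated correlation), among them Ccl5, a chemokine made by T cells, with a log2 fold change of 2.61 ± 0.24. Of 22 type I interferon response genes, Ifit2, Irf7 and Zbp1 rose (5 adjusted over the list alone; list adjusted p = 5.65e-05, and 0.446 with an estimated correlation). Of 16 MHC class I genes, 5 rose, among them Psmb9 and Erap1 (9 adjusted over the list alone; list adjusted p = 8.01e-06, and 0.264 with an estimated correlation). Irf7 and Zbp1 each lost their call in 4 of the 11 fits that left out a library, without IgG replicate 1, IgG replicate 4 or 3xTx replicate 4 for both, and their highest adjusted p there was 0.0871 and 0.101.

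Neutrophil genes rose in 6 of 16 cases (7 adjusted over the list alone), with Il1b, interleukin-1 beta, at 56 ± 10.5 CPM against 15.7 ± 5.72 CPM and Acod1, the enzyme that makes itaconate, at 11.1 ± 4.72 CPM against 1.91 ± 0.194 CPM. The list's adjusted p was 2.63e-05, and 0.198 with an estimated correlation. Of 18 dendritic cell genes 4 rose, among them Wdfy4 and Irf8, and Cacnb3 and Socs2 fell (5 up and 2 down adjusted over the list alone; list adjusted p = 0.0381, and 0.198 with an estimated correlation). This list lost its call in 8 of the 11 fits that left out a library, including each fit without a 3xTxNK library, where its adjusted p was 0.108 to 0.121. Of 12 B and plasma cell genes Cd22 and Ighm rose (3 adjusted over the list alone), and the list did not pass (adjusted p = 0.0996). Cell cycle genes rose in 17 of 24 cases (24 adjusted over the list alone), with Top2a, a topoisomerase of dividing cells, at 660 ± 78.4 CPM against 379 ± 60.2 CPM. That list had a median of 0.55 (adjusted p = 9.54e-17), and its call was lost with an estimated correlation (adjusted p = 0.0954).

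Fibroblast and matrix genes fell in 7 of 18 cases (9 adjusted over the list alone), with a median of -0.36 (adjusted p = 8.01e-06, and 0.0201 with an estimated correlation). Fn1, fibronectin, was at 947 ± 271 CPM in 3xTx against 2100 ± 319 CPM in IgG, while Col1a1 was at 701 ± 138 CPM against 736 ± 110 CPM (log2 fold change -0.07, interval -0.38 to 0.24). Of 21 squamous epithelium genes only Itgb4, an integrin of the basement membrane contact, fell (1 adjusted over the list alone), and the list did not pass (adjusted p = 0.715), with a median of 0.16 and a mean of 0.09 beside a test direction of down. Egfr, the mouse gene of the EGF receptor, was at 76.6 ± 10.8 CPM against 81.8 ± 11.5 CPM (log2 fold change -0.10, interval -0.36 to 0.17). Krt14, a basal keratin, was at 74.4 ± 36.9 CPM against 62.6 ± 59.1 CPM. Of 15 endothelial genes Cldn5, a tight junction protein of vessels, fell (1 adjusted over the list alone; list adjusted p = 0.121). Itgb4 lost its call in 6 and Cldn5 in 3 of the 11 fits that left out a library, with a highest adjusted p of 0.0768 and 0.0781. None of 15 hypoxia and glycolysis genes passed (0 adjusted over the list alone), and the list's call as lower (adjusted p = 0.0358) was lost with an estimated correlation (adjusted p = 0.588). It was also lost without IgG replicate 1, 3 or 4 or 3xTx replicate 4, where the adjusted p reached 0.148.

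Markers of tissue that can be dissected with a subcutaneous tumour were counted beside these groups. None of 17 skeletal muscle genes passed, with a median of 1.00 (list adjusted p = 0.186) that rested on 3xTx replicate 3 and was negative without it, nor any of 10 mast cell genes (0.0844) or 6 differentiated skin and hair genes (0.472). Of 8 lymph node stroma genes Ltb, which activated lymphocytes also express, rose (5.9 ± 0.773 CPM against 1.39 ± 0.324 CPM), with a list median of -0.04, a mean of 0.07 and an adjusted p of 0.715. Adjusted over the list alone, Ltb was the single call among these lists. The 4 tested adipose and 3 tested red blood cell genes, too few for a list test, gave no call.

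The largest rises and falls in 3xTx included genes outside these lists. Trbv16, a variable segment of the T cell receptor beta chain, had no count in the 4 IgG libraries and 1.02 ± 0.681 CPM in 3xTx, at least 29.6-fold higher than the floor of 3 counts over the IgG group (0.0343 CPM). Cd5l, a protein secreted by macrophages, was at 7.12 ± 3.25 CPM against 0.15 ± 0.134 CPM, and Cd226, an activating receptor of T and NK cells, at 2.79 ± 1.08 CPM against 0.0971 ± 0.123 CPM. Kcna2 and Gbp2b completed the 5 largest rises. With almost no counts in IgG, the sizes of their log2 fold changes (5.87 ± 1.2 and 4.71 ± 0.78) are uncertain and moved to 8.92 without IgG replicate 1 and to 7.21 without IgG replicate 3, and Kcna2 lost its call with limma-voom. The falls were led by Pcsk2, a prohormone convertase (0.284 ± 0.131 CPM against 4.34 ± 2.66 CPM), and Zbtb16 (ENSMUSG00000066687), a transcription factor induced by glucocorticoids (1.31 ± 0.789 CPM against 13.1 ± 3.97 CPM, log2 fold change -3.11 ± 0.39). Zcchc5 and the protease inhibitors Serpina3m and Serpina3n, which belong to a family that can share reads, fell by 2.99, 2.85 and 2.69 on the log2 scale.

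In the comparison of 3xTx with IgG, edgeR called 1238 genes without IgG replicate 1 and 1409 to 2230 in the other fits that left out an IgG or 3xTx library. Of the 24 lists tested, camera with its preset correlation called 17, 15 upward and 2 downward, and 10 of these held with an estimated correlation, whereas other splits of the same 8 libraries gave up to 19 lists with the preset correlation and at most 0 with an estimated one.

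**Figure D1:**
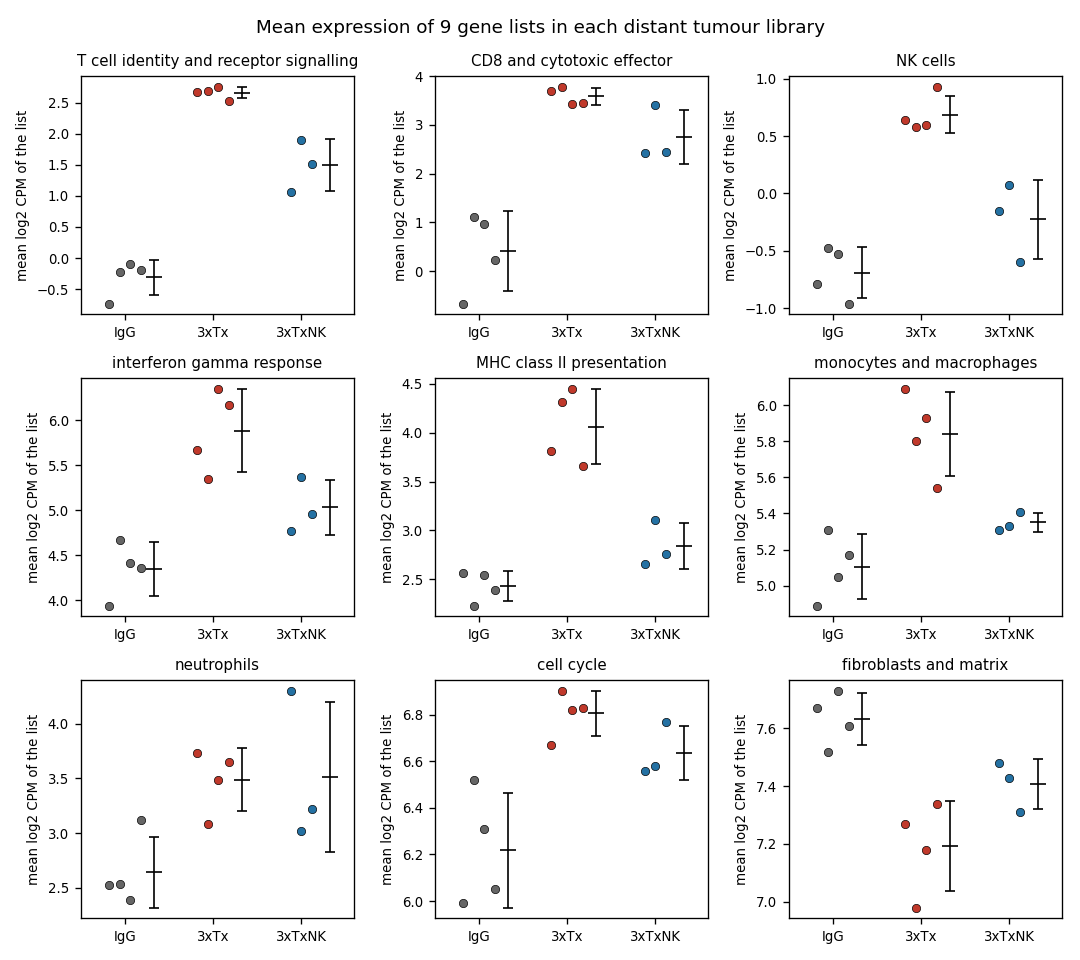
Mean log2 CPM of 9 gene lists in each of the 11 libraries, by group. Points are libraries, and the bar beside them is the group mean ± SD. The T cell list lay between 2.53 and 2.75 in the 4 3xTx libraries, between -0.73 and -0.1 in the 4 IgG libraries and between 1.07 and 1.9 in the 3 libraries labelled 3xTxNK.

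The comparison of 3xTxNK with 3xTx asks how the depleting antibody changed the distant tumour under the same treatment. None of the 3 groups received the antibody alone, so whether the treatment's effect depends on it is not tested here. As lists, MHC class II and T cell transcripts were lower in the libraries labelled 3xTxNK, with 7 of 11 and 1 of 19 genes past the threshold over all genes. The granzyme and perforin transcripts Gzmb and Prf1 did not pass, and their means in 3xTxNK leaned on replicate 2. H2-Ab1 was at 33.9 ± 13.9 CPM in 3xTxNK (n = 3) against 99.7 ± 21.9 CPM in 3xTx (n = 4), a log2 fold change of -1.55 ± 0.27 (adjusted p = 0.0234). Cd8a was at 11.8 ± 2.91 CPM against 28.3 ± 2.4 CPM (-1.26 ± 0.25, adjusted p = 0.0343) and Cxcl9 at 41.6 ± 16.9 CPM against 130 ± 31.3 CPM (-1.65 ± 0.29, adjusted p = 0.0234). In all, 209 of 19806 genes (1.06%) changed, 65 upward and 144 downward, and the groups did not overlap in 16.4% of the tested genes, where chance gives 5.71%. Every one of the 22 named calls of this comparison was lost without 3xTxNK replicate 1, which left 1 call, and without 3xTxNK replicate 3, which left 3. The count was 94 without 3xTxNK replicate 2, 66, 100 and 67 without 3xTx replicate 1, 2 and 3, and 362 without IgG replicate 2, which enters through the shared estimate of the spread.

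MHC class II genes fell in 7 of 11 cases (9 adjusted over the list alone), with a median of -1.33 (adjusted p = 9.07e-18, and 0.0248 with an estimated correlation). H2-Eb1 was at 29.1 ± 10.5 CPM against 90.3 ± 26.3 CPM, and Ctss, the protease that trims the invariant chain, at 231 ± 11.2 CPM against 381 ± 43.5 CPM. Of 19 T cell genes Trbc2 fell (5.24 ± 2.36 CPM against 15.8 ± 1.59 CPM), and 15 fell adjusted over the list alone. The list's median was -1.24 (adjusted p = 1.15e-16, and 0.0248 with an estimated correlation). None of 15 NK cell genes passed (1 adjusted over the list alone), with a list median of -1.06 (adjusted p = 1.39e-05, and 0.0248 with an estimated correlation). Chemokines and receptors fell in 4 of 27 cases, among them Ccl5, Cxcl9 and Cxcl16 (12 adjusted over the list alone), with a median of -0.86 (adjusted p = 3.92e-10, and 0.0326 with an estimated correlation). These 4 lists were the ones whose calls held with an estimated correlation, of 18 called with the preset one.

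The other lists called lower lost their call with an estimated correlation. CD8 and cytotoxic effector genes fell in 4 of 19 cases, namely Cd8a, Ccl5, Klrd1 and Klrk1 (8 adjusted over the list alone; list median -1.05, adjusted p = 2.05e-09, and 0.18 with an estimated correlation). Klrd1, a receptor chain of T and NK cells, was at 3.48 ± 0.73 CPM against 10.3 ± 2.76 CPM. Gzmb was at 36 ± 19.6 CPM against 41.9 ± 11.8 CPM (log2 fold change -0.20, interval -1.04 to 0.65), and Prf1 at 21.9 ± 13 CPM against 23.8 ± 5.73 CPM (-0.09, interval -0.9 to 0.71). These means leaned on 3xTxNK replicate 2, at 58.6 CPM of Gzmb and 36.9 CPM of Prf1. Replicates 1 and 3, at 24.6 and 24.8 CPM of Gzmb and 15.5 and 13.3 CPM of Prf1, lay below every 3xTx library. Macrophage genes fell in 5 of 18 cases (10 adjusted over the list alone; list adjusted p = 1.3e-10, and 0.0604 with an estimated correlation), with Csf1r at 80.7 ± 9.04 CPM against 145 ± 23.4 CPM and Adgre1 at 12.2 ± 2.29 CPM against 35.9 ± 10 CPM. Interferon gamma response genes fell in 4 of 22 cases (17 adjusted over the list alone; list adjusted p = 1.15e-16, and 0.0927 with an estimated correlation), among them Cxcl9. Of 12 B and plasma cell genes Ighm fell (1.86 ± 0.136 CPM against 7.63 ± 3.11 CPM; 3 adjusted over the list alone; list adjusted p = 0.00587, and 0.0935 with an estimated correlation).

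Of the lists called lower with no member past the threshold over all genes, type I interferon response had 16 of 22 members lower adjusted over the list alone (list adjusted p = 3.92e-12, and 0.188 with an estimated correlation). Checkpoints had 5 of 12 (1.66e-06, and p = 0.0735 with an estimated correlation), dendritic cells 2 of 18 (0.00331, and p = 0.0935), interleukin-2 signalling 2 of 13 (0.0104, and p = 0.111), and MHC class I 0 of 16 (7.99e-07, and p = 0.237). Cell cycle had 0 of 24 (0.00205, and p = 0.552 with an estimated correlation), skeletal muscle 0 of 17 (0.00641, and p = 0.605) and mast cells 0 of 10 (0.00259, and p = 0.246). The lists called higher were fibroblasts and matrix (0.00195, and p = 0.0935 with an estimated correlation), where Dcn, the proteoglycan decorin, rose to 697 ± 174 CPM from 379 ± 72 CPM (5 up and 1 down adjusted over the list alone), and hypoxia and glycolysis (0.00205, and p = 0.491), with no member past the threshold. The skeletal muscle median, -1.38 with all libraries, was 0.23 without 3xTx replicate 3. Skeletal muscle and hypoxia lost their calls without 3xTxNK replicate 2 (adjusted p = 0.181 and 0.201), and mast cells without 3xTx replicate 1 (0.0907). Neutrophil genes were not called as a list (adjusted p = 0.702), with a median of 0.09 and a mean of 0.15 beside a test direction of down; Acod1 fell, and 1 rose and 2 fell adjusted over the list alone. Regulatory T cell (0.543), squamous epithelium (0.615), endothelium (0.826), skin and hair (0.37) and lymph node stroma (0.502) lists were not called and held no call, except 1 lymph node member lower adjusted over the list alone. The 4 adipose and 3 red blood cell genes held no call.

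The largest rises in 3xTxNK were of Zbtb16 (9.32 ± 4.57 CPM against 1.31 ± 0.789 CPM, adjusted p = 0.0144), Ncam2, Sdk2, Ace, the angiotensin-converting enzyme (172 ± 8.91 CPM against 50.4 ± 21.3 CPM), and Hmcn1. The largest falls were of Ighm, Treml4 (2.32 ± 0.246 CPM against 8.61 ± 3.54 CPM), Kcnj10, Fam26f and Acod1 (3.39 ± 0.928 CPM against 11.1 ± 4.72 CPM). Pdcd1, Cd4 and Cd274 did not pass, at log2 fold changes of -1.12, -1.15 and -0.79 and adjusted p of 0.0897, 0.0957 and 0.0953. Ifng (adjusted p = 0.441), Foxp3 (0.404), Cd3e (0.317), Krt14 (0.57), Col1a1 (0.981) and Egfr (0.714) did not pass either. Over the fits that left out a library, Sdk2 lost its call in 10 of 11, Treml4 and Dcn in 9, Hmcn1, Ighm and Adgre1 in 6, and Ace and Zbtb16 in 2.

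**Figure D2:**
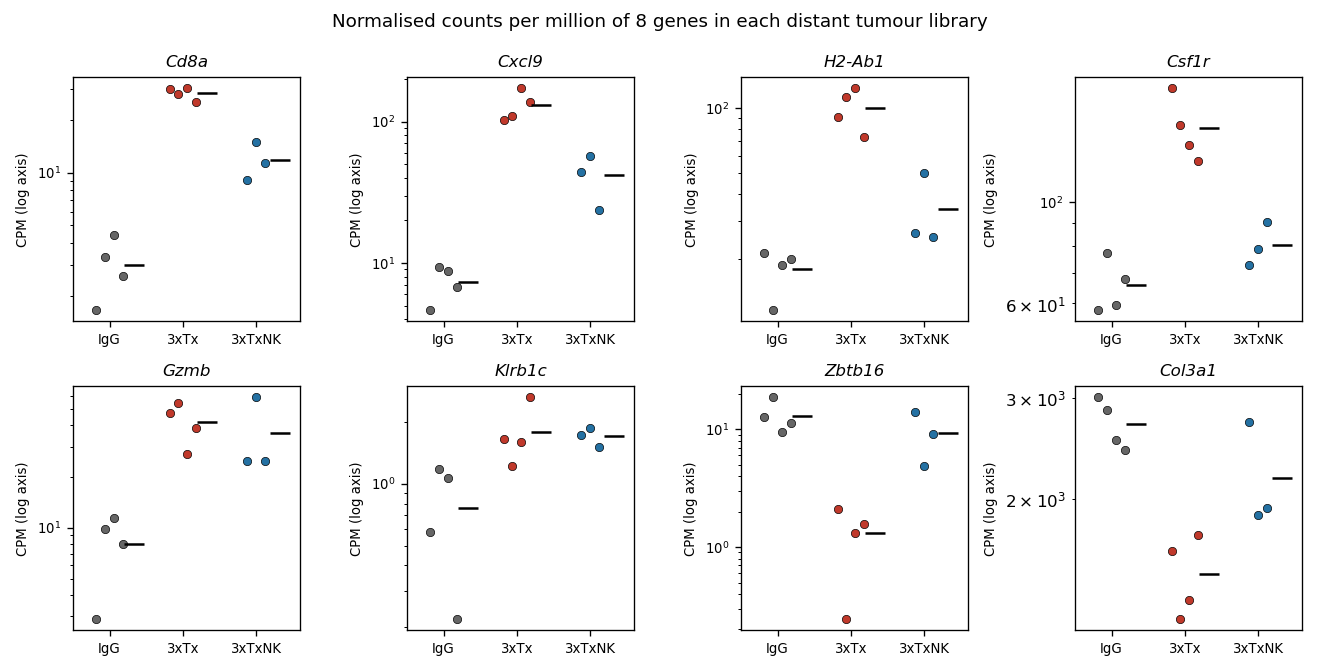
Normalised CPM on a log axis of 8 genes in each of the 11 libraries. Points are libraries and the short bar is the group mean. Cd8a lay at 25 to 30.1 CPM in 3xTx and at 9.1 to 14.9 CPM in the libraries labelled 3xTxNK, whereas Klrb1c lay at 1.22 to 2.63 and 1.5 to 1.87 CPM.

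The comparison of 3xTxNK with IgG changes the treatment and the depleting antibody together, so it gives the effect of neither alone. T cell and cytotoxic transcripts were higher in the libraries labelled 3xTxNK, with the granzyme cluster among the largest rises. Gzmg (ENSMUSG00000040284) was at 59.1 ± 40.4 CPM in 3xTxNK (n = 3) against 1.46 ± 0.937 CPM in IgG (n = 4), a log2 fold change of 5.35 ± 0.6 (adjusted p = 0.00649). The 3xTxNK libraries stood at 46.7, 104 and 26.3 CPM, the change was 4.65 without 3xTxNK replicate 2, and the call was lost with limma-voom and its sample quality weights. Cxcl9 rose by 2.5 ± 0.29 to 41.6 ± 16.9 CPM (adjusted p = 0.00649) and Cd8a by 1.97 ± 0.26 to 11.8 ± 2.91 CPM (adjusted p = 0.00976). In all, 72 of 19806 genes (0.364%) changed, 62 upward and 10 downward, and 12% of the tested genes had groups that did not overlap, where chance gives 5.71%. The count was 12 without 3xTxNK replicate 2, 39 and 37 without 3xTxNK replicates 1 and 3, 38 and 23 without IgG replicates 1 and 4, 42 and 43 without 3xTx replicates 1 and 4, and 117 without IgG replicate 2. It was 8 when only these groups were fitted.

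CD8 and cytotoxic effector genes rose in 12 of 19 cases (18 adjusted over the list alone), with a median of 2.04 (adjusted p = 4.32e-49, and 0.0201 with an estimated correlation). Gzmd, Gzme and Gzmg can share reads. Gzmb was at 36 ± 19.6 CPM against 8.01 ± 3.69 CPM and Prf1 at 21.9 ± 13 CPM against 5.1 ± 2.27 CPM, but Gzmb lost its call in 9 and Prf1 in 8 of the 11 fits that left out a library. T cell genes rose in 7 of 19 cases (18 adjusted over the list alone), with a median of 1.81 (adjusted p = 9.19e-37, and 0.0143 with an estimated correlation). Cd3d was at 2.6 ± 1.45 CPM against 0.335 ± 0.161 CPM and Bcl11b at 1.47 ± 0.0849 CPM against 0.2 ± 0.107 CPM. These were the lists whose calls held with an estimated correlation, of 13 called with the preset one.

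Other lists called higher lost their call with an estimated correlation. Among checkpoints Pdcd1 (4.54 ± 1.07 CPM against 0.785 ± 0.34 CPM) and Ctla4 rose, 2 of 12 (3 adjusted over the list alone; adjusted p = 5.88e-07, and 0.116 with an estimated correlation). Ctla4 alone rose among 10 regulatory T cell genes (3 adjusted over the list alone; camera adjusted p = 0.0175, and 0.244 with an estimated correlation), and this list's median turned to -0.03 without IgG replicate 2 and -0.06 without 3xTxNK replicate 2, with no call. Il2rb and Il7r rose among 13 interleukin-2 signalling genes (4 adjusted over the list alone; 0.000277, and p = 0.0965 with an estimated correlation), and Ccl5 and Cxcl9 among 27 chemokine genes (7 adjusted over the list alone; 0.000104, and p = 0.154). Cxcl9 alone rose among 22 interferon gamma response genes (5 adjusted over the list alone; camera adjusted p = 7.85e-10, and 0.181 with an estimated correlation), and Plk1 and Foxm1 rose among 24 cell cycle genes (15 adjusted over the list alone; 1.42e-16, and p = 0.154). No neutrophil gene of 16 passed (7 adjusted over the list alone; 3.13e-08, and p = 0.154 with an estimated correlation), nor any of 11 MHC class II genes (6 adjusted over the list alone; 0.000264, and p = 0.176), where H2-Ab1 was at 33.9 ± 13.9 CPM against 17.9 ± 4.32 CPM (adjusted p = 0.165). No macrophage gene of 18 passed (1 adjusted over the list alone; camera adjusted p = 0.0179, and 0.439 with an estimated correlation), and this call was lost without IgG replicate 1, IgG replicate 3 or 3xTxNK replicate 3.

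Lower lists were fibroblasts and matrix (adjusted p = 0.00527, and 0.154 with an estimated correlation), where Postn, periostin, fell to 34.5 ± 1.59 CPM from 83.3 ± 33 CPM (1 adjusted over the list alone), and endothelium (0.0185, and p = 0.453), with no member past the threshold. The fibroblast call was lost without 3xTxNK replicate 3 (adjusted p = 0.065), and the endothelium call without IgG replicate 2, IgG replicate 4 or 3xTxNK replicate 2 (0.104, 0.148 and 0.267). The NK cell (adjusted p = 0.139), type I interferon (0.105), MHC class I (0.402), B and plasma cell (0.796), squamous epithelium (0.368), hypoxia (0.931), skeletal muscle (0.36), mast cell (0.57) and lymph node stroma (0.931) lists were not called. The dendritic cell list was not called (0.961) with a median of 0.09 and a mean of -0.02, nor was the skin and hair list (0.961) with a median of -0.05 and a mean of -0.36 beside a test direction of up. Adjusted over the list alone, 1 squamous gene was lower, and the skin and lymph node lists each had 1 higher and 1 lower. The adipose and red blood cell genes held no call.

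Ctsg, a protease of neutrophils and mast cells, had no count in IgG and 1.26 ± 0.788 CPM in 3xTxNK, at least 36.6-fold higher than the floor of 3 counts over the IgG group (0.0343 CPM). That bound leans on 3xTxNK replicate 2, at 2.16 CPM against 0.916 and 0.696 CPM in replicates 1 and 3, and the call was lost without it (adjusted p = 0.0568) and when only these groups were fitted. Klrg1, a receptor of effector T and NK cells, was at 1.38 ± 0.62 CPM against 0.066 ± 0.104 CPM and lost its call in 8 of the 11 fits that left out a library. The largest falls were of Postn, Fmo1 (71.7 ± 7.22 CPM against 161 ± 41 CPM), Cd109, Klhdc8a and Ypel3. Postn lost its call in 9 and Klhdc8a and Plk1 in 10 of those 11 fits, whereas Gzmg, Gzmd, Gzme, Cd8a, Cxcl9, Pdcd1 and Bcl11b kept theirs in all 11. Under other settings, limma-voom lost Gzmg, Gzmd and Gzme among 8 of the 23 named calls, and the fit of only these groups lost Cd8a, Pdcd1 and Bcl11b among 18. Cd3e (adjusted p = 0.0679), Ifng (0.37), Cd274 (0.11), Cd4 (0.952), Klrb1c (0.324), Ncr1 (0.953), Foxp3 (0.563), Krt14 (0.706), Col1a1 (0.928) and Egfr (0.933) did not pass.

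**Figure D3:**
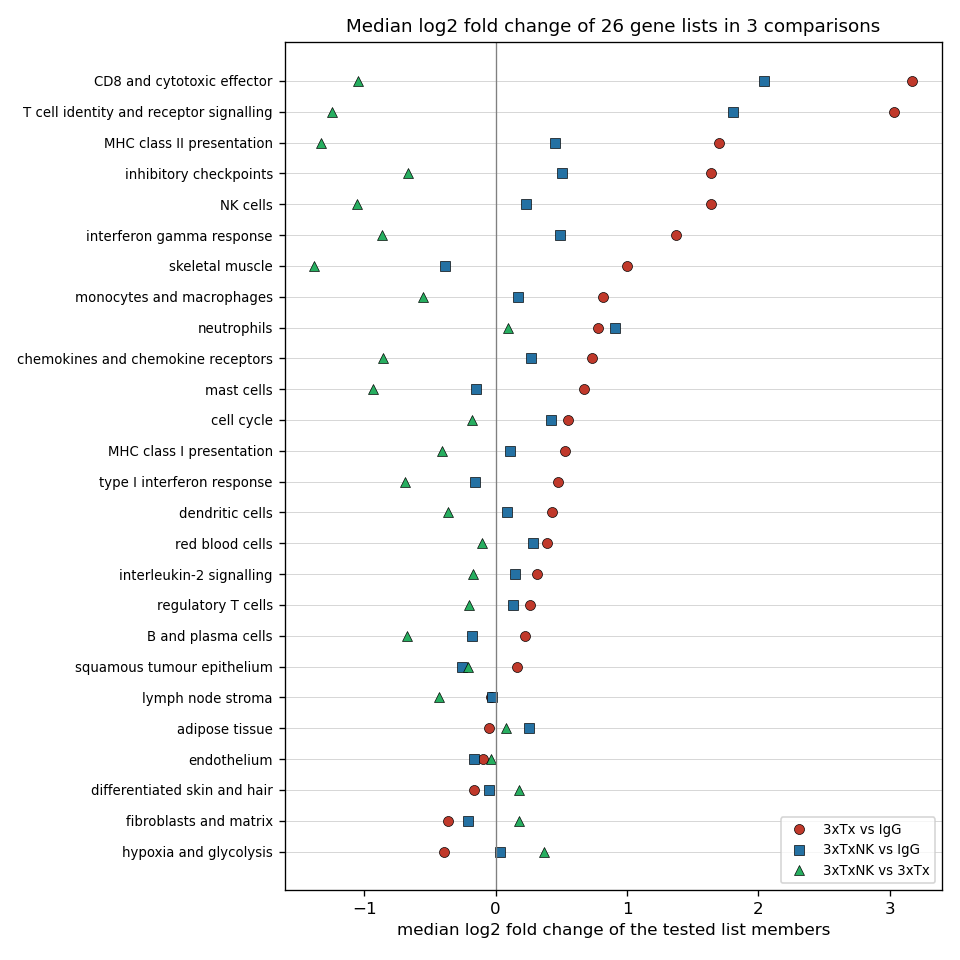
Median log2 fold change of 26 gene lists in the 3 comparisons, 1 line per list and 1 marker per comparison. The T cell list stood at 3.03 in 3xTx against IgG, at 1.81 in 3xTxNK against IgG and at -1.24 in 3xTxNK against 3xTx.

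Of the genes raised in 3xTx against IgG, 140 were lowered in 3xTxNK against 3xTx, among them Cd8a, Cxcl9, H2-Ab1 and Csf1r, and 55 genes lowered in the first comparison were raised in the second, among them Zbtb16 and Dcn. Both comparisons use the 3xTx libraries, whose chance values push them in opposite directions. In 50 simulations of unchanged groups the overlaps were 0 and 0 genes. With no group changed, almost no gene can pass, so an overlap near 0 was fixed in advance and does not test the reversal. Independent lists of these sizes would share 8.35 and 2.58. With separate pairs of 3xTx libraries for the comparisons the 6 fits gave 0 to 88 and 0 to 22 genes. Across genes, which are not independent replicates, the fold changes of the comparisons had a correlation of -0.54, against -0.47 in the simulations and -0.18 with split libraries. Their covariance was -0.208 against a simulated -0.0842, a difference of -0.124. Both overlaps vanished or nearly so without 3xTxNK replicate 1 (0 and 1 genes) and without 3xTxNK replicate 3 (0 and 2). They were 48 and 17 without 3xTx replicate 1, 73 and 20 without 3xTx replicate 2, 47 and 19 without 3xTx replicate 3, 68 and 24 without 3xTxNK replicate 2, 106 and 31 without IgG replicate 4, and 205 and 125 without IgG replicate 2.

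Between 3xTx against IgG and 3xTxNK against IgG, 68 genes changed the same way, 60 raised in both, among them Cd8a, Cxcl9, Pdcd1 and Gzmb, and 8 lowered in both. These comparisons share the IgG libraries. The simulations of unchanged groups gave 0 genes, which was fixed in advance here too. Independent lists would share 3.6 raised and 0.396 lowered genes, and the 6 fits with the IgG libraries split gave 0 to 73 genes. The correlation across genes was 0.68, against 0.47 in the simulations and 0.21 with split libraries, and the covariance 0.297 against a simulated 0.084, a difference of 0.213. The overlap was 11 without 3xTxNK replicate 2, 39 and 36 without 3xTxNK replicates 1 and 3, 35 and 23 without IgG replicates 1 and 4, 115 without IgG replicate 2, and 41 and 43 without 3xTx replicates 1 and 4.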

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

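Of the tests in this part, the counts over other splits of the libraries with the preset correlation were planned, those with an estimated correlation were added once the preset counts had been seen, and the list contrasts, the thinned and covariate fits and the tests of the Klrb1c pattern were chosen only after the results were seen.

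T cell transcripts were higher in 3xTx than in IgG, with a list median of 3.03. Depth alone is argued against by thinning every library to the shallowest, which left a median of 2.86 (camera adjusted p = 7.01e-28 with the preset correlation). Thinning evens out the totals only. Other differences between libraries that may have gone with the groups, as depth did, were not tested by it. RNA quality as read from the mitochondrial share is argued against by a fit with that share as a covariate, which gave 3.23 (camera adjusted p = 4.03e-49). Both fits were tested with the preset correlation only, so the argument rests on the medians and not on these p-values. Lymph node tissue in the 3xTx pieces would carry B cells too, yet the T cell list rose by 2.61 more on the log2 scale than the B cell list. The difference was at least 2.42 with any 1 library left out. The exact permutation test (two-sided p = 0.0286, the smallest that 70 arrangements allow) adds little, since the T cell list alone already set these groups apart. In the B cell list Ighm and Cd22 did rise, with log2 fold changes of 3.15 and 1.51, and 10 members did not pass. A treatment effect on the number or activity of T cells at the distant site stays as a hypothesis, and these libraries cannot separate number from activity.

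T cell and MHC class II transcripts were lower in the libraries labelled 3xTxNK than in 3xTx, with 209 genes that differ. Thinned to the shallowest library, the MHC class II median was -1.53 (camera adjusted p = 6.28e-20 with the preset correlation). With the mitochondrial share as a covariate it was -1.33 (camera adjusted p = 2.31e-16). The size of the thinned median argues against depth as the whole source. The mitochondrial share hardly differed between these groups (5.07 ± 1.18% in 3xTx and 4.92 ± 1.44% in 3xTxNK). As a covariate it could therefore move the median little, and RNA quality in other respects was not tested. The p-values add little, since the thinned and covariate fits were tested with the preset correlation only. A lower share of all leukocytes stays open. It would lower neutrophil transcripts as well, and the T cell list mean minus the neutrophil list mean changed by -1.19 (exact permutation test, two-sided p = 0.0286, the smallest that 35 arrangements allow). The change was -0.59 without 3xTxNK replicate 1, whose neutrophil mean of 4.3 log2 CPM lay above 3.02 and 3.22 in replicates 2 and 3, and 3xTxNK replicate 2 (-1.12) lay next to 3xTx replicate 4 (-1.11). An effect of the depleting antibody stays open beside it, and the call of every named gene depends on 3xTxNK replicates 1 and 3.

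Klrb1c, the gene of NK1.1, was not lower in the libraries labelled 3xTxNK. A library of the 3xTx group among those labelled 3xTxNK is argued against by the T cell list, whose highest mean among the 3 libraries, 1.9 log2 CPM, lay below the lowest of 3xTx, 2.53. An exchange of the labels 3xTx and 3xTxNK would leave NK cell genes higher in 3xTxNK. The mean of 8 others, each of at least 1 CPM in the higher of these groups, was lower there by 1.03 (a change of -1.03, exact permutation test, two-sided p = 0.0286). It was lower by at least 0.86 with any 1 library left out. This direction goes against an exchange, but T cells can express some of these genes, and the T cell list was lower too. The genes belong to the NK cell list already seen to be lower, so the p-value is no separate evidence. Some entered through 3xTx alone, such as Klre1 (2.46 CPM in 3xTx and 0.913 CPM in 3xTxNK). Reads shared with the Klrb1 paralogs stay open, since Klrb1b, the most abundant of them, had a log2 fold change of -1.14 that did not pass (adjusted p = 0.273). A sample from outside these groups, depletion that had waned by day 12, and NK1.1 transcripts in T cells were not tested.

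For the gene counts of all 3 comparisons chance could be excluded only at 1 in 35, the least that 35 splits allow. That share was not adjusted over the tests of this paragraph. In 1 of the 35 splits, the real one, as many genes were called, with 1934 genes for 3xTx against IgG and at most 0 in another split, 209 for 3xTxNK against 3xTx and at most 9, and 72 for 3xTxNK against IgG and at most 4. For gene lists called with the preset correlation chance could not be excluded. The real splits gave 17, 18 and 13 lists, and 4, 2 and 9 of the 35 splits gave as many, with up to 19, 18 and 15 in another split. With an estimated correlation chance could be excluded in each comparison at the same 1 in 35, also not adjusted. Only the real split gave the 10, 4 and 2 lists, with at most 0, 2 and 0 in another. For the overlaps, 100 regroupings of the 11 libraries were drawn. The 140 genes raised and then lowered were matched by 2 of them (real one included, highest other 200), the 55 lowered and then raised by 4 (91), and the 68 changed the same way by 3 (334), so chance could be excluded only as a random mixing of all 11 libraries. The regroupings with counts as large kept the whole 3xTx or the whole IgG group together, a structure of the samples. These counts thus show that a shared group stands apart, and chance in the reversal or the agreement itself was not tested by them.

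Among 224 sets of IgG or 3xTx values tested for a library that stands apart, 9 gave one. That is no more than the about 1 in 20 that chance gives, so the values below do not show that these libraries differ. The tests share libraries and genes, so the count does not show that the libraries are alike either. The shallowest library, 3xTx replicate 2, was not flagged, and no 3xTxNK library was tested. IgG replicate 2 had a total of 19.3 M counts (other IgG libraries 22.6 to 23.2 M), a share of 5.56% in its 10 most abundant genes (7.36 to 7.57), 2.94% mitochondrially encoded counts (4.02 to 4.14) and a hypoxia list mean of 6.4 log2 CPM (7.23 to 7.36). IgG replicate 1 had 6.5 CPM of Adgre1 (12.2 to 12.8), 0.223 CPM of Cd3e (1.28 to 1.55), 0.089 CPM of Kcna2 (0 in the others), 0.267 CPM of Treml4 (0.87 to 1.05) and 55.8 CPM of Ypel3 (47.3 to 48.6).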

How the results depend on the processing

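No gene called in both the reported fit and an alternative changed sign, and named genes kept their side of the threshold in 2768 of the cases run, lost it in 331, gained it in 18 and reversed in 0. Lists kept it in 1665, lost it in 89, gained it in 31 and reversed in 3. The cause of a change was not tested except where fewer samples or genes entered. With 3xTx against IgG the count stayed within 1.5 times of 1934 under every setting except leaving out IgG replicate 1, and the depth of the shallowest library limits what the thinned fits can call.

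Counts are given for 3xTxNK against 3xTx, 3xTxNK against IgG, genes raised in 3xTx and then lowered in 3xTxNK, genes lowered and then raised, and genes changed the same way (209, 72, 140, 55 and 68 as reported). DESeq2 gave 858, 470, 415, 264 and 363, limma-voom with sample quality weights 864, 151, 439, 230 and 131, no filter on low counts 475, 239, 236, 166 and 207, and an adjusted p under 0.1 gave 551, 187, 282, 191 and 167. Among calls of 3xTxNK against 3xTx, 65 of 209 were rises as reported, against 371 of 858 with DESeq2, 363 of 864 with limma-voom and 220 of 475 with no filter. For 3xTxNK against IgG, 62 of 72 were rises, against 311 of 470 with DESeq2. With only the 2 groups compared, 3xTxNK against IgG gave 8 and the same-way overlap 7. Leaving out the shallowest library and thinning the others to the smallest IgG total (chosen after seeing the data) gave 111, 47, 79, 23 and 45. Thinning to the shallowest library (also chosen after) gave 30 for 3xTxNK against IgG and 30 for the same-way overlap, and the mitochondrial share as a covariate (also chosen after) gave 83 genes lowered and then raised.

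Leaving out 1 library at a time gave 1238 to 2230 genes for 3xTx against IgG, 1 to 362 for 3xTxNK against 3xTx, 12 to 117 for 3xTxNK against IgG, 0 to 205 raised and then lowered, 1 to 125 lowered and then raised, and 11 to 115 changed the same way. Fewer libraries enter these fits. A reversal here is a list whose test direction changed while at least 1 of the fits called it, and a median that changed sign alone is not one. The reversals were of the list skeletal muscle, 3xTxNK vs 3xTx, without 3xTx replicate 3 (medians -1.89 to 0.235 over the libraries left out), of the list hypoxia and glycolysis, 3xTxNK vs IgG, without IgG replicate 2 (-0.16 to 0.11), and of squamous epithelium in 3xTxNK against 3xTx (0.432) with the number in the description as the block.

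The replicate numbers did not pair the samples: deviations from the group means of the 10 pairs of libraries with the same title number had a mean correlation of -0.03 (-0.14 to 0.06), and the 7 pairs with the same number in the description 0.01 (-0.09 to 0.09), with 0 pairs above 0.1. With the replicate block of the title number, 3xTxNK against IgG gave 28 genes, the raised and then lowered overlap 87 and the same-way overlap 26. With the block by the number in the description, 3xTxNK against IgG gave 22 and the same-way overlap 21.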

Other observations

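The further lists of glucocorticoid and ERK target genes were written before their values were seen, after called genes had drawn attention to them, and the granzyme contrast was chosen only after its values were seen. Values are mean log2 CPM ± SD, and tests are two-sided exact permutation tests. The 9 tests run were adjusted together, and none passed (lowest adjusted p = 0.0858). Those not given below were as follows. Glucocorticoid targets changed by 0.49 in 3xTxNK against 3xTx and by -0.31 in 3xTxNK against IgG. ERK targets changed by -0.16 in 3xTx against IgG and by 0.21 in 3xTxNK against IgG. The granzyme C to G mean minus the T cell list mean changed by 0.76 and 2.21 in these last comparisons.

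Transcripts of T cell receptor variable segments were counted together. Beta chain segments summed to 0.222 ± 0.161 CPM in IgG, 5.76 ± 2.55 CPM in 3xTx and 1.55 ± 0.549 CPM in 3xTxNK, and alpha chain segments to 0.383 ± 0.214, 2.22 ± 0.844 and 1.38 ± 0.443 CPM. With every library thinned to the shallowest, beta segments with a count numbered 0 to 0 in IgG, 7 to 11 in 3xTx and 3 to 5 in 3xTxNK, while alpha segments, at 0 to 4, 5 to 9 and 3 to 6, overlapped between 3xTxNK and each other group. Immunoglobulin kappa variable segments were at 2.79 ± 1.7, 1.95 ± 1.68 and 1.72 ± 1.54 CPM, and heavy chain variable segments at 0.91 ± 0.761, 1.46 ± 1.23 and 1.16 ± 0.685 CPM.

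Some genes that glucocorticoids induce were lower in 3xTx than in IgG. The metallothionein Mt1 was at 101 ± 39 CPM against 246 ± 66.7 CPM, Fkbp5, a co-chaperone of the glucocorticoid receptor, at 87.1 ± 19.4 CPM against 197 ± 54.1 CPM, and Per1, a clock gene, at 51.2 ± 20.5 CPM against 128 ± 18.3 CPM, whereas Sgk1 did not pass (100 ± 11.6 CPM against 87.8 ± 10.6 CPM). A candidate explanation is weaker glucocorticoid signalling in the distant tumour. Of 12 further target genes 4 were lower and 8 did not pass. Their mean changed by -0.8 (exact p = 0.0286, the smallest that 70 arrangements allow; lower in 4 of 4 libraries), which does not pass adjusted over the 9 tests (0.0858), so these libraries are too few to decide. Composition stays open, since fibroblast transcripts also fell while Egfr and Col1a1 had log2 fold changes of -0.10 and -0.07, and so does time of day or handling at collection, which was not tested.

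Spry4 and Dusp6, which restrain ERK signalling, rose in 3xTxNK against 3xTx, Spry4 by 0.77 (73.9 ± 7.77 CPM against 43.4 ± 4.77 CPM, adjusted p = 0.0138) and Dusp6 by 0.55 on the log2 scale (384 ± 19.2 CPM against 262 ± 17.5 CPM, adjusted p = 0.0166), whereas Spry1 did not pass (adjusted p = 0.383). The hypothesis of stronger ERK signalling with the depleting antibody was tested on 13 further targets, of which 0 passed singly. Their mean changed by 0.36 (exact p = 0.0286, the smallest that 35 arrangements allow; higher in 3 of 3 libraries), which does not pass adjusted over the 9 tests (0.0858) and leaves this open. Spry4 and Dusp6 in IgG were at 63.6 ± 2.96 and 347 ± 21.8 CPM. Both were lower in 3xTx than in IgG (log2 fold changes -0.55 and -0.4, edgeR adjusted p = 0.00382 and 0.00706). Neither passed in 3xTxNK against IgG (edgeR adjusted p = 0.44 and 0.533). Their difference between 3xTxNK and 3xTx thus goes with a lower level in 3xTx.

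Granzymes C to G did not pass in 3xTxNK against 3xTx, with log2 fold changes of -0.10 for Gzmc to 0.73 for Gzmg, while the T cell list was lower. The change of Gzmg leaned on 3xTxNK replicate 2, at 104 CPM against 46.7 and 26.3 CPM in replicates 1 and 3, beside 36.7 ± 18.5 CPM in 3xTx. A higher granzyme level per T cell may be behind it. The granzyme mean minus the T cell list mean changed by 1.45 between 3xTxNK and 3xTx (exact p = 0.0857, adjusted 0.154), which leaves this open, and these genes can share reads.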
